A study of Mus musculus with 2 samples.

How the data were processed

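The data are gene and transcript tables of total RNA sequencing from 2 libraries, each of 100 mouse hematopoietic stem cells, which the labels call biological replicates 1 and 2. The labels give both the same strain, sex and donor identifier under different biosample identifiers, and whether the pools came from separate animals is not given in the sources used here, so the spread between them may be partly technical. Expected counts were deposited by the authors as estimated reads per gene and per transcript, with reads that match several places shared out, and they are not all whole numbers. TPM values were deposited by the authors as well, scaled to a fixed total per library, and a posterior mean TPM stands beside them per the file headers. FPKM values were deposited in the same tables and are proportional to TPM within a library. The percent of a gene's signal carried by each transcript was deposited with the transcript tables. The genome build is mm10 and the annotation GENCODE release M4, per the text deposited with each sample, and the column names are those the program RSEM writes, per the file headers. The aligner, the version of the quantification program, trimming and the handling of strand are not given in the sources used here.

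Each gene table has 69691 rows, of which 43346 carry a mouse Ensembl gene identifier. The 96 spike-in sequences, a phiX sequence and 26248 numbered entries name no gene and were left out of library comparisons. The numbered entries held 0% of expected counts in replicate 1 and 1.73e-05% in replicate 2, and the spike-ins 0.012% and 0.00712%. Symbols came from a table of gene names and from the GENCODE M21 annotation of GRCm38, the same build, and 42462 identifiers (98.0%) matched. Of the genes detected in both libraries, 70 had no symbol. Positions and biotypes are those of GENCODE M21, and a neighbouring ribosomal RNA pseudogene was taken from the RefSeq table of the same build. Of the listed symbols, 3 had no match (Hbb-b1, Snhg1, and Emr1, an older name of Adgre1).

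With a single group of 2 libraries no test between groups was possible, and no p-value across genes is given. A gene was called detected at a TPM of at least 1 and an expected count of at least 10. Levels are TPM with mean and SD over the libraries, differences are on the log2(TPM + 1) scale, which understates those of low genes, and ratios within a library use a pseudocount of 0.1 TPM. Lists were described by their median, set among 10000 random lists of as many protein coding genes, and list differences by their place among 10000 random lists matched on mean expression in 20 classes. Lists for 12 cell types and 7 cell states, and lists of transcription factors, receptors, Y chromosome genes, Xist and Tsix, and abundant non-coding RNAs, were fixed before the data were examined. Common dispersion was estimated with edgeR 4.0.16 on expected counts rounded to whole numbers, with TMM factors and its expression filter, and its square root is the biological coefficient of variation. DESeq2 1.42.0 gave size factors for alternatives, in R 4.3.3. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

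Most genes named in the text were set by a rule fixed before the data were examined. They are the 5 members of highest mean TPM per list (12 for the stem, transcription factor and receptor lists), all sex-linked list members, genes of the ratios and Hox genes detected in both libraries. They also include the 10 most abundant genes outside the mitochondrial genome, the 5 genes furthest higher in each replicate among those with at least 100 counts in the higher library and a mean of at least 10 TPM, and stem and transcription factor members not detected in both. Camp, Fcnb, Ltf, Ighm, Jchain, other members of the antibody and granulocyte sets, the mitochondrial genes, their nuclear copies, and the histone, MHC class II and Gimap genes were named after their values were seen, as were Gfi1 and Ikzf2 for their transcripts.

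Shares of counts carry 95% exact binomial intervals, and a count of 0 is given an upper limit of 3 counts. Reads amplified by PCR without molecular identifiers are not independent molecules, so these intervals and limits cover counting error only. Some members that this rule names, and 1 of the planned ratios, are not given. The steps were tested on simulated data. The dispersion step returned 0.394 for a simulated coefficient of variation of 0.4 over 13256 genes. For list differences between the libraries, over 13238 simulated genes, 100% of 100 lists of 12 genes changed 4-fold were recovered and 2% of unchanged lists were called. The simulated genes varied independently with a coefficient of variation of 0.4, so smaller differences and lists of genes regulated together were not covered. Alternatives were the TPM and count thresholds, the pseudocount, FPKM, posterior mean TPM, rescaled TPM, other normalisations, other gene filters, another background for the lists, and leaving out each library. TPM rescaled over nuclear protein coding genes, for detection and list differences, agreement over those genes, and the other background for the cell state lists were added after seeing the data.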

Results

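Total RNA from 2 pools of mouse hematopoietic stem cells was sequenced, each library being made from 100 cells. Hematopoietic stem cells are rare bone marrow cells that renew themselves and give rise to every blood lineage. The labels number the libraries as biological replicates 1 and 2 of a single group of adult male C57BL/6J mice, so no second condition was compared. The profile answers which genes the pools expressed, whether markers of other marrow cells were present, and how far the replicates differed. A pool of 100 cells cannot assign a transcript to a cell type, and how the cells were gated is not given in the sources used here. The deposited expected counts summed to 48313341 in replicate 1 and 28947093 in replicate 2. Levels are given in TPM (transcript abundance scaled to a fixed total per library) as mean ± SD of the 2 libraries (n = 2 throughout), and a gene was called detected at 1 TPM or more with an expected count of at least 10.

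Of the 20 members of the stem list, 16 were detected in both libraries. Hlf, a transcription factor of long-lived stem cells, stood at 129.8 ± 45.1 TPM, and Kit, the receptor for stem cell factor, at 112 ± 6.69 TPM. Ifitm1 was measured at 85.0 ± 14.7 TPM, Meis1 at 73.5 ± 18.7 TPM, and Ly6a, which encodes the sorting marker Sca-1, at 36.2 ± 15.4 TPM. Mecom, which encodes a zinc finger factor needed for stem cell upkeep, was at 52.0 TPM in replicate 1 and 17.9 TPM in replicate 2. Mllt3 (31.1 ± 5.15 TPM), Pdzk1ip1 (18.4 ± 14.7 TPM), Gata2 (15.9 ± 4.37 TPM), Procr (4.88 ± 2.26 TPM) and Robo4 (3.95 ± 0.94 TPM) followed. The SLAM family gene Slamf1, which encodes the stem cell marker CD150, reached 2.87 TPM in replicate 1 and 0.36 TPM in replicate 2, from expected counts of 237 and 18. Sult1a1 (0.18 and 0.76 TPM), Ndn (0 and 0.43 TPM) and Hoxb5 (0 and 0.16 TPM) were likewise not detected in both libraries. An expected count of 0 in replicate 1 allows up to 0.0611 TPM of Ndn and 0.0421 TPM of Hoxb5, for counting error only. The levels themselves are not bounded so closely, as 26.1% of nuclear coding genes at 1 to 3 TPM in replicate 2 had no count in replicate 1. The median of the list was 8.69 TPM in replicate 1 and 7.25 TPM in replicate 2, at percentiles 97.0 and 95.9 among 10000 random lists of as many protein coding genes. Both lie below the percentile 97.5 that is used below to call a cell type list high. Against lists drawn from genes detected in either library instead, the mean percentile was 32.5.

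**Figure D1:**
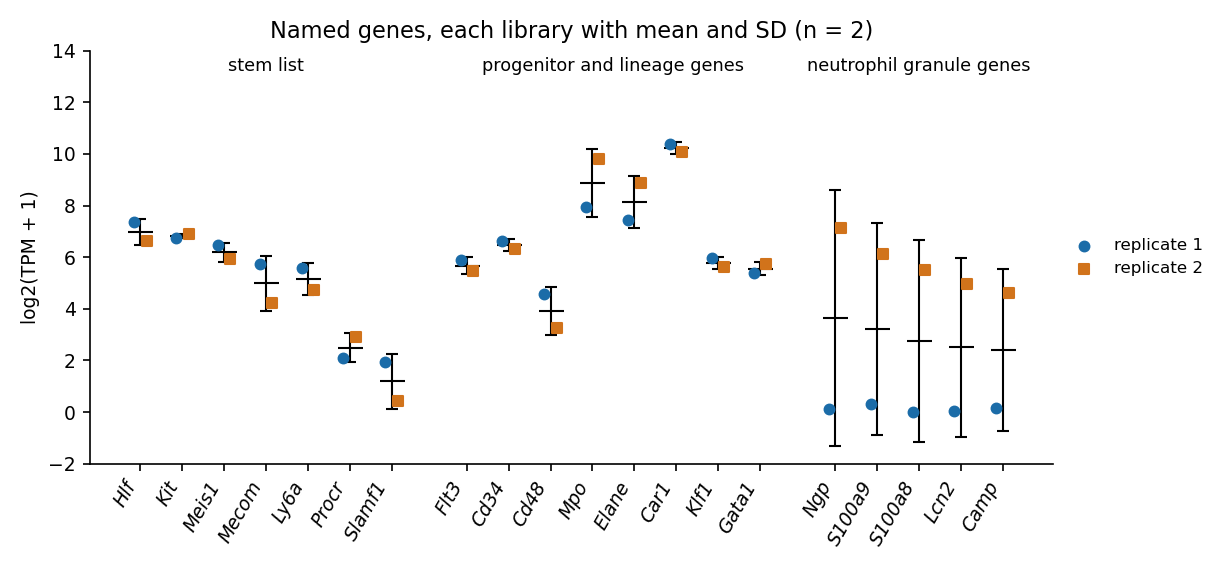
Levels of named genes on the log2(TPM + 1) scale, with replicate 1 as circles, replicate 2 as squares, and the mean with its SD (n = 2) in black. Kit was within 107.5 to 117 TPM, while Ngp was at 0.09 TPM in replicate 1 and 139.5 TPM in replicate 2.

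Genes of multipotent and lymphoid-primed progenitors were present, with 10 of 12 detected in both libraries. Cd34 stood at 88.1 ± 14.1 TPM, the tumour necrosis factor receptor gene Cd27 at 70.8 ± 26.9 TPM, the receptor tyrosine kinase gene Flt3 at 50.8 ± 11.1 TPM and Satb1 at 47.7 ± 9.28 TPM. The early myeloid list had 9 of 12 members detected in both libraries, led by the granule enzymes Mpo (246 TPM in replicate 1 and 891 TPM in replicate 2) and Elane (172 and 463 TPM). Ly6c2 was at 140.01 ± 10.2 TPM, Prtn3 at 71.0 ± 35.7 TPM and Csf3r at 55.0 ± 1.77 TPM. All 13 measured erythroid genes were detected in both libraries, and the carbonic anhydrase genes Car1 (1202 ± 185 TPM) and Car2 (368 ± 5.27 TPM) were the most abundant of them. The globin genes Hba-a2 and Hba-a1, paralogs for which read sharing was not tested, were estimated at 222 ± 2.31 and 172 ± 21.8 TPM, and the blood group gene Ermap at 149 ± 26.3 TPM. These 3 lists were the only ones of 12 cell type lists whose median lay above the percentile 97.5 of random lists in both libraries. Their medians were 29.7 ± 2.51 TPM (multipotent and lymphoid-primed), 28.3 ± 11.3 TPM (early myeloid) and 86.6 ± 16.7 TPM (erythroid). Against lists drawn from genes detected in either library, 2 lists passed, and the mean percentile of the early myeloid list was 96.9.

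Markers of mature and non-blood cells were mostly low, apart from the mature neutrophil and monocyte list in replicate 2. Of the megakaryocyte list, 6 of 12 genes were detected in both libraries, led by Itga2b at 16.3 ± 7.09 TPM, then Vwf at 7.21 ± 3.30, Selp at 4.47 ± 0.10 and Gp9 at 3.58 ± 0.95 TPM, whereas the platelet factor gene Pf4 had no counts in replicate 1 and 9.67 TPM in replicate 2. The B cell list had 3 of 12 detected in both, with Cd79a at 7.39 ± 0.05 TPM and Blnk at 4.30 ± 2.00 TPM, and Igll1 (9.73 TPM), Cd79b (5.83 TPM) and Pax5 (4.54 TPM) had counts in replicate 2 and none in replicate 1. The T and NK cell list had 3 of 13, with Nkg7 at 46.0 ± 13.9 TPM, Ncr1 at 4.39 ± 3.75 TPM and Lck at 4.07 ± 4.07 TPM, and with Klrb1c (7.24 and 0.43 TPM) and Cd3e (3.56 and 0 TPM) detected in replicate 1 alone. The mast cell, basophil and eosinophil list had 3 of 10, with Prg2 at 31.8 TPM in replicate 1 and 1.79 TPM in replicate 2, Cpa3 at 3.61 ± 0.80 TPM and Mcpt8 at 2.12 ± 0.97 TPM, while Hdc (0.01 and 4.96 TPM) and Ms4a2 (0 and 0.71 TPM) were not detected in both. The macrophage list had 1 of 10 (Cd68, 5.27 ± 0.28 TPM), with Vcam1 (0 and 3.73 TPM), Cd163 (1.16 and 0.12 TPM), Mrc1 (0 and 0.30 TPM) and Siglec1 (0 and 0.06 TPM) below detection in a library. The endothelial list had 2 of 10 (Pecam1, 28.3 ± 10.9 TPM, and Emcn, 2.59 ± 1.01 TPM), and Plvap, Flt4 and Sox18 were each under 2 TPM in both libraries. The stromal and bone list had 1 of 11 (Pdgfrb, 5.14 ± 0.88 TPM), with Alpl, Col1a2 and Sparc under 1 TPM and no counts on Pdgfra. The mature neutrophil and monocyte list had 2 of 12 in both libraries, with a median of 0.02 TPM in replicate 1 and 16.6 TPM in replicate 2.

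**Figure D2:**
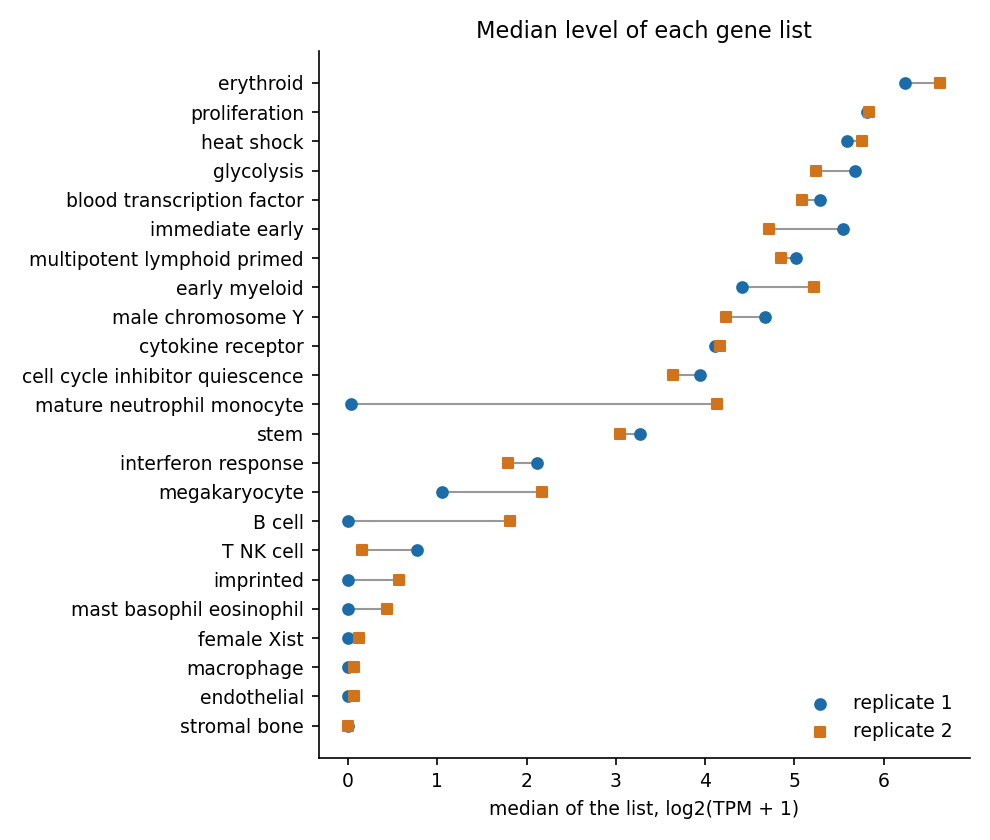
Median level of each gene list, apart from abundant non-coding RNAs, on the log2(TPM + 1) scale, replicate 1 as circles and replicate 2 as squares, joined by a line. Of the lists shown, erythroid and proliferation lists had the highest mean levels (86.6 and 55.9 TPM), and the mature neutrophil and monocyte list shows the widest gap (0.02 and 16.6 TPM).

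Regulators of blood cell identity were broadly expressed, and 36 of 40 transcription factor and receptor genes were detected in both libraries. Lmo2, an adaptor of the Tal1 complex, was highest at 292 ± 143 TPM, followed by Myb at 191 ± 6.81, Ikzf1 at 149 ± 29.2, Runx1 at 99.1 ± 20.1 and Etv6 at 97.3 ± 39.1 TPM. The erythroid and megakaryocytic regulators Gfi1b (64.9 ± 7.28 TPM), Klf1 (54.4 ± 9.32 TPM) and Gata1 (46.3 ± 8.08 TPM) had higher means than Erg (43.6 ± 20.4 TPM), Lyl1 (39.3 ± 10.6 TPM), Fli1 (34.8 ± 0.83 TPM) and Tal1 (30.3 ± 10.7 TPM). In replicate 1, however, Gata1 (40.6 TPM) lay below Erg (58.0 TPM) and Lyl1 (46.7 TPM). The myeloid factor gene Cebpa (0.25 and 4.14 TPM) and the B-lineage factor genes Ebf1 (0.01 and 3.12 TPM) and Pax5 (0 and 4.54 TPM) were the factors not detected in both. Among receptors beside Kit, Flt3 and Csf3r, Ifngr1 was at 51.0 ± 8.65, Cxcr4 at 46.8 ± 14.2, Notch2 at 32.7 ± 3.34, Csf2ra at 22.5 ± 8.89, Notch1 at 20.96 ± 4.54, Il6st at 18.3 ± 11.5, Epor at 17.1 ± 7.71 and Ifnar1 at 14.5 ± 4.45 TPM. The medians of the lists were 35.5 ± 3.54 TPM for transcription factors and 16.6 ± 0.45 TPM for receptors.

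Hox expression fell on the A cluster, where 7 of 11 genes were detected in both libraries. Hoxa9 was highest at 33.1 ± 12.7 TPM, then Hoxa7 at 12.8 ± 0.73, Hoxa3 at 11.99 ± 7.03, Hoxa6 at 8.01 ± 2.63, Hoxa5 at 3.95 ± 0.76, Hoxa2 at 1.66 ± 0.17 and Hoxa4 at 1.32 ± 0.10 TPM. Of the 10 B cluster genes, Hoxb3 alone was detected in both (2.71 ± 0.25 TPM), and of the 9 C and 9 D cluster genes none was. The D cluster genes had no counts in either library. The 4 genes of the Y chromosome list were detected in both libraries, with Eif2s3y at 26.7 ± 5.13, Uty at 24.3 ± 1.17, Ddx3y at 18.4 ± 10.01 and Kdm5d at 13.4 ± 1.08 TPM. Xist had expected counts of 0 and 8 and Tsix of 0 and 12, which matches the male label of both pools.

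Ratios within a library, in which depth and scaling cancel apart from the pseudocount, placed Gata2 below Gata1, with a log2 ratio of -1.56 ± 0.15 (n = 2, pseudocount 0.1 TPM), as they did Spi1 (-0.71 ± 0.16). Slamf1 lay below Cd48 (-3.59 ± 0.90), a gene of more committed progenitors that stood at 23.0 TPM in replicate 1 and 8.51 TPM in replicate 2. Procr lay below Cd34 (-4.21 ± 0.91), and the cell cycle inhibitor gene Cdkn1c lay below the proliferation gene Mki67 (-6.41 ± 1.77). Spi1 itself stood at 28.1 ± 1.79 TPM. Each of these ratios was below 0 in both libraries by more than the spread between them, but an exact two-sided sign-flip test on 2 libraries cannot give a p under 0.5.

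Proliferation genes were strongly expressed, all 18 being detected in both libraries with a median of 55.9 ± 0.65 TPM. Mki67 was at 215 ± 18.5, Mcm3 at 196 ± 43.9, Top2a at 169.8 ± 8.66, Mcm6 at 126 ± 30.5 and Pcna at 118 ± 15.5 TPM. Cell cycle inhibitors and quiescence genes were also expressed, with 11 of 13 detected in both, a median of 12.9 ± 2.07 TPM, and Rbl1 (41.8 ± 0.79 TPM), Rb1 (35.0 ± 7.77 TPM), Foxo3 (33.2 ± 3.08 TPM), Rbl2 (33.1 ± 1.98 TPM) and Btg2 (19.1 ± 0.65 TPM) at the top. Cdkn1c stood at 5.56 TPM in replicate 1 and 1.03 TPM in replicate 2. Immediate early genes, which are induced within minutes by growth factors and by cell handling, had a median of 35.5 ± 14.3 TPM with 13 of 15 detected in both, led by Zfp36 (177 ± 77.5 TPM), Dusp1 (137 ± 43.4 TPM), Fos (124 ± 37.1 TPM), Jun (98.6 ± 27.0 TPM) and Egr1 (68.2 ± 35.7 TPM). The heat shock list had a median of 50.3 ± 4.35 TPM with 9 of 10 detected, led by the chaperone genes Hspa8 (1648 ± 227 TPM), Hsp90ab1 (848 ± 42.5 TPM) and Hsp90aa1 (561 ± 54.9 TPM), and with Hspa1b at 73.5 ± 11.9 and Hspd1 at 58.0 ± 18.2 TPM. Glycolysis genes (16 of 17 detected in both, median 43.6 ± 9.41 TPM) were led by Gapdh at 752 ± 64.7, Ldha at 133 ± 9.26, Gpi1 at 129 ± 24.7, Aldoa at 123 ± 7.11 and Eno1 at 86.2 ± 0.78 TPM. The interferon response list was lower, with 7 of 13 detected in both and a median of 2.89 ± 0.62 TPM, although Oasl2 (29.3 ± 18.96 TPM), Irf9 (25.2 ± 12.6 TPM), Irf7 (10.4 ± 10.2 TPM) and Stat2 (6.38 ± 0.97 TPM) were detected. Of 13 imprinted genes, 5 were detected in both libraries, namely Gnas (206 ± 12.6 TPM), Grb10 (13.3 ± 3.32 TPM), Igf2r (8.07 ± 2.20 TPM), Cdkn1c and Phlda2 (2.25 ± 0.05 TPM). The proliferation, inhibitor, immediate early, heat shock and glycolysis lists, 5 of these 7, had medians above the percentile 97.5 of random protein coding lists in both libraries. Against genes detected in either library 4 did, and the mean percentile of the inhibitor list was 74.1.

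Non-coding and ribosomal transcripts made up most of the signal, since nuclear protein coding genes held 28.3 ± 2.46% of TPM. Gm42418, annotated as a long intergenic RNA at chromosome 17, 39846958 to 39848788 on the plus strand (GRCm38), was the most abundant gene outside the mitochondrial genome, at 297776 TPM in replicate 1 and 409479 TPM in replicate 2. It overlaps a pseudogene related to 18S ribosomal RNA, Rn18s-rs5, by 1245 bp in the RefSeq annotation of the same build. With its neighbour Gm26917 (10301 ± 2625 TPM) it held 30.6% and 42.2% of TPM. The mitochondrial ribosomal RNAs held 23.9 ± 4.09%, and the 13 mitochondrial coding genes 3.23 ± 0.59%. Among the other abundant genes outside the mitochondrial genome were the 7SK RNA gene Rn7sk (19672 ± 3911 TPM), the immunoglobulin light chain gene Igkc (9780 ± 2743 TPM), the elongation factor gene Eef1a1 (5572 ± 509 TPM), Mir6236 (5086 ± 1286 TPM), Gm29216 (4040 ± 924 TPM), a kappa variable gene of the Igkv1 family (3926 ± 5513 TPM; chromosome 6, 67609713 to 67610508), the RNase P RNA gene Rpph1 (3751 ± 263 TPM) and Gm10925 (3122 ± 3713 TPM). Gm10925 and Gm29216 are annotated as unprocessed pseudogenes on chromosome 1. Gm10925 shares sequence with the mitochondrial gene mt-Atp6, so its level is uncertain. Gm29216 lies near it, at 24615706 to 24616197, and whether it shares reads with a mitochondrial gene was not settled. Of the abundant non-coding list, 6 of 8 measured genes were detected in both, including Malat1 (2907 ± 244 TPM), Rmrp (842 ± 94.0 TPM) and Gas5 (231 ± 61.3 TPM).

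**Figure D3:**
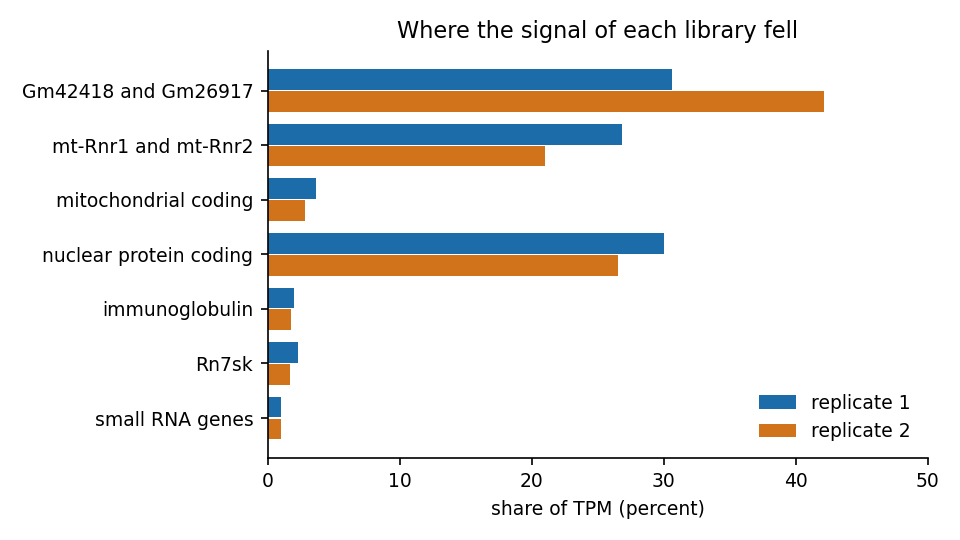
Share of TPM, in percent, held by each group of genes in replicate 1 and replicate 2. Gm42418 and Gm26917 together held 30.6% and 42.2%, and nuclear protein coding genes 30.03% and 26.6%.

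Spike-in sequences took a small share of the libraries. They held 0.012% of expected counts in replicate 1 (95% exact binomial interval 0.0117 to 0.0123) and 0.00712% in replicate 2 (0.00681 to 0.00743), so the share differed beyond counting error. Of the 96 sequences, 20 and 25 had any count. The log2 ratio of counts between the libraries had an SD of 0.52 over the 10 spike-ins with at least 10 counts in both, against 1.05 over 8243 genes in the same count range.

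Between the libraries, 10685 genes were detected in both, of which 9780 were protein coding, while 766 passed in replicate 1 alone and 1411 in replicate 2 alone. Although replicate 1 had 1.88 times as many counts on nuclear protein coding genes, 10464 protein coding genes had no count there, against 8292 in replicate 2. Of 1640 nuclear coding genes at 1 to 3 TPM in replicate 2, 26.1% (exact interval 24.0 to 28.3) had no count in replicate 1, whereas 2.58% (1.77 to 3.62) of 1242 such genes of replicate 1 had none in replicate 2. Across the 12862 genes detected in either library, which are not independent replicates, log2(TPM + 1) had a Pearson r of 0.828 and a Spearman rho of 0.838, with a median absolute difference of 0.53 and 72.9% of genes within 2-fold. The share within 2-fold was 91.5% among genes with a mean of 100 TPM or more and 61.1% among those under 10 TPM. A chi-square over the counts of 14337 genes came to 151 per degree of freedom, which covers counting error only and shows no more than that they are not a single library deposited a second time. The biological coefficient of variation was 0.411 over 11666 genes by edgeR's common dispersion. That value rests on a filter that asks for counts in both libraries, and it was 0.56 over genes with a mean count of at least 50 and 1.01 without a filter.

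**Figure D4:**
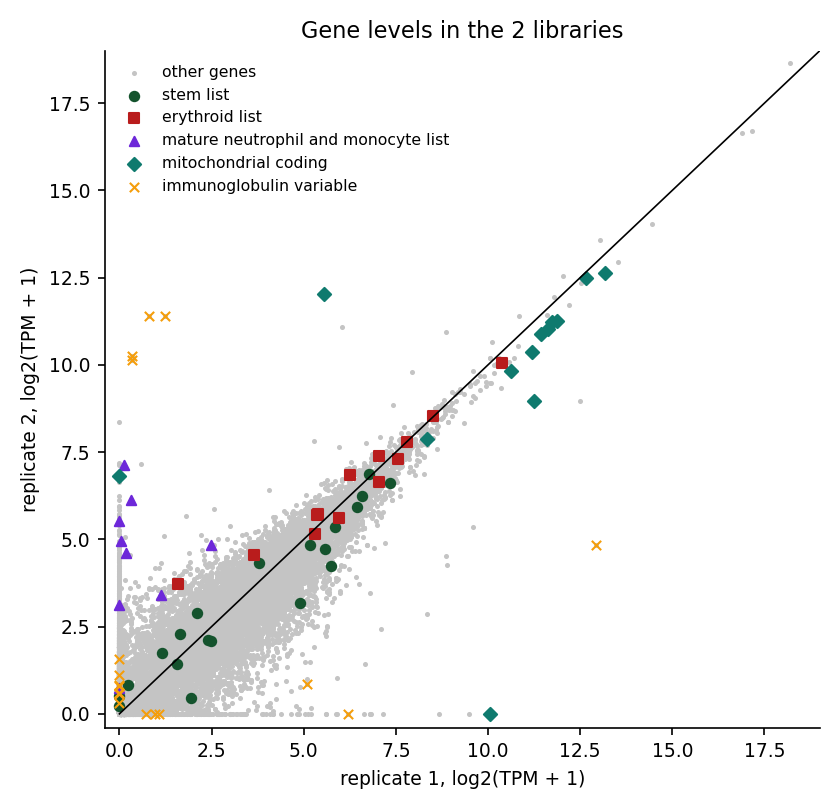
Gene levels in replicate 1 (x axis) against replicate 2 (y axis), both log2(TPM + 1), with the line of equality and selected gene groups in colour. Most erythroid genes lie near the line, 3 stem genes were over 2-fold higher in replicate 1, and most neutrophil genes with signal, several immunoglobulin variable genes and 4 mitochondrial coding genes lie far from it (Pearson r of 0.828 over 12862 genes).

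Some gene lists differed between the replicates, beside the wide spread of single genes given above. The mature neutrophil and monocyte list was higher in replicate 2 by a median of 4.45 log2 units among its 9 members with signal (listed as -4.45 for replicate 1 minus 2, and -2.73 over all 12 members), with the granule and alarmin genes Ngp (0.09 and 139.5 TPM), S100a9 (0.24 and 69.1 TPM), S100a8 (0 and 45.0 TPM) and Lcn2 (0.04 and 30.01 TPM), and the lysozyme gene Lyz2 (4.61 and 27.8 TPM). The early myeloid list lay at -1.08, with 7 of 12 members over 2-fold higher in replicate 2, the megakaryocyte list at -0.85 and the B cell list at -1.26. The immediate early list was higher in replicate 1 (0.59), as was the interferon response list (0.71), with 6 members over 2-fold higher there, among them Irf7 (17.5 and 3.18 TPM). These were the 6 of 24 lists whose median difference fell outside the central 95% of 10000 random lists matched on mean expression, where the median over coding genes was -0.03. For the mature neutrophil list the difference depended on the scale, at -3.16 with TMM-normalised CPM, -5.97 with rescaled TPM and -6.69 with a pseudocount of 0.1, always outside that range. The megakaryocyte list moved inside the range with a pseudocount of 0.1 (-1.46, percentile 8.15) and with rescaled TPM (-1.22, percentile 6.24). The B cell list did so with TMM-normalised CPM (-0.77). The T and NK cell list (0.24) moved outside the range with a pseudocount of 0.1 (0.67) and with rescaled TPM (0.39), higher in replicate 1. The stem list (0.31), the proliferation list (0.00) and the erythroid list (-0.03) stayed inside it.

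Among single genes with at least 100 counts in the higher library and a mean of at least 10 TPM, those that differed most included immunoglobulin variable genes, a mitochondrial gene and short RNA genes. The Igkv1 family gene at chromosome 6, 67609713 to 67610508 (GRCm38), had an expected count of 60169 in replicate 1 and 117 in replicate 2, whereas Igkv4-55 had 10 and 10904, Igkv5-39 had 4 and 7684, Ighv6-3 had 2 and 4966 and Ighv1-53 had 2 and 4562. The snRNA gene Gm26244 had 0 and 256 counts. The mitochondrial gene mt-Co2 had 18979 and 0 counts, and 3 short RNA genes, Mir1938 (113 and 0), Gm27640 (154 and 0) and Gm27533 (134 and 0), were seen in replicate 1 alone. Mitochondrial genes with nuclear copies share sequence with them, so the level of any single such gene is uncertain, and read sharing between immunoglobulin variable genes was not tested.

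The transcript tables were compared for genes with at least 2 annotated transcripts. Of 7571 such genes detected in both libraries, 51.8% (exact interval 50.6 to 52.9) had the same most abundant transcript in both. Among the blood transcription factors this held for 11 of 15, including Gata1, whose main transcript held 98.7 ± 1.91% of the gene's signal, Lmo2 (89.9 ± 5.01%), Tal1 (89.8 ± 14.4%) and Spi1 (81.8 ± 8.27%). Runx1, Erg, Gfi1 and Ikzf2 had different leading transcripts, and the leading Gfi1 transcript of replicate 1 held 81.4% there and 0% in replicate 2.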

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

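No test in this part was planned before the data were examined. Beside the gene measurements, 17 expected counts fell on the phiX sequence, a sequencing control, in replicate 2 and 0 in replicate 1. A single numbered entry without a gene name held 5 expected counts in replicate 2 and 0 in replicate 1. Each lies above the limit of 3 counts that a count of 0 allows, and no explanation was weighed for either.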

How the results depend on the processing

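Rescaled TPM (over nuclear protein coding genes) was planned for the list levels, and was added after seeing the data for detection and list differences, as were agreement over nuclear protein coding genes and the background of detected genes for the cell state lists. Detected genes ranged from 7495 (5 TPM) to 11270 (0.5 TPM), within 1.5 times of 10685. With rescaled TPM 10379 passed, counted over nuclear protein coding genes alone, against 9780 protein coding genes with TPM as deposited. The counts of high lists, detected regulators, Hox genes and differing lists also stayed within 1.5 times, and the ratios and the isoform share moved by less than their spread or interval. The Pearson r of 0.828 moved to 0.709 (pseudocount 0.1), 0.88 (pseudocount 5), 0.941 (all genes), 0.718 (mean TPM of at least 10), 0.845 (FPKM), 0.85 (posterior mean TPM), 0.9002 (TMM-normalised CPM), 0.9004 (DESeq2 size factors) and 0.862 (nuclear coding genes), and the cause was not tested. The biological coefficient of variation of 0.411 became 0.56 with a mean count of at least 50 and 1.01 without a filter, both of which let in genes absent from a library. The stem list percentile of 96.4 became 99.8 by mean log2(TPM + 1) and 32.5 against genes detected in either library, a background without silent genes. With rescaled TPM the stem median went from 7.97 to 28.1 and the proliferation median from 55.9 to 198, by construction, and the latter was 54.2 with posterior means. The spike-in share was 0.0187% of TPM against 0.00954% of counts, and nuclear coding genes held 38.2% of counts against 28.3% of TPM, since the units weigh length differently. Leaving out a library kept every count of detected genes, lists, regulators and Hox genes within 1.5 times. Without replicate 1 the high cell type lists went from 3 to 4, the mature neutrophil and monocyte list being added. Of 200 other comparisons, 138 kept their value or call. No list difference outside the central 95% of random lists changed sign, but inside it that of the mast cell, basophil and eosinophil list did (0.36, and -0.80 with TMM-normalised CPM), and lists near 0 crossed it where all coding genes shifted (median -0.12 with TMM-normalised CPM and -0.19 with rescaled TPM). At 100 cells a library, genes under 10 TPM are measured least closely.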

Other observations

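The tests on mitochondrial genes, on immunoglobulin genes, and on depth and recovered molecules for the neutrophil genes were chosen after the results were seen, and the test on a second set of granulocyte genes was written before those genes were looked at. Gene families outside the fixed lists were also expressed. Of 67 replication-dependent histone genes, whose transcripts lack a poly(A) tail, 53 were detected in both libraries, with a summed level of 7120 ± 1128 TPM (SD, n = 2), and Hist1h4d (1675 and 1161 TPM) was the highest. Of 83 cytosolic ribosomal protein genes, 80 were detected in both, with a summed level of 25610 ± 3130 TPM. All 7 MHC class II genes examined were detected in both, Cd74 at 42.9 ± 4.35 TPM and H2-Ab1 at 51.0 TPM in replicate 1 and 13.1 TPM in replicate 2. Of 8 Gimap genes, 5 were detected in both, with Gimap6 at 57.5 ± 0.90 TPM and Gimap4 at 38.2 TPM in replicate 1 and 2.76 TPM in replicate 2.

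Of the 13 mitochondrial coding genes, 9 were higher in replicate 1 by 0.18 to 0.84 log2 units, while mt-Co2 (18979 and 0 counts), mt-Atp6 (822 and 41703), mt-Nd3 (0 and 443) and mt-Nd4l (13661 and 1501) lay more than 2 units apart, in both directions. A different mitochondrial RNA content of the pools would shift them alike, which is argued against for these 4 genes by their opposite directions. The SD of the 13 differences, as log2(TPM + 1), was 4.05, but it follows from these same 4 genes and is no separate test. Each of the 4 has a nuclear copy on chromosome 1 that shares at least 50% of its 31-base words, such as Gm10925 for mt-Atp6 (chromosome 1, 24613974 to 24614651, GRCm38), with 102452 and 4943 counts. Among the other 9 genes, mt-Co3 (copy Gm28437) and mt-Nd4 (copy Gm28439) have such copies as well, so a copy is not particular to the 4. After summing each gene with its copy, their median absolute log2 difference in counts per library total (CPM + 1) went from 5.18 to 0.46, although mt-Nd3 stayed 1.86 apart, and all 13 genes were then higher in replicate 1, with an SD of 0.39. Read sharing between mitochondrial genes and near-identical nuclear copies is therefore a candidate explanation for the 4 genes, while a higher mitochondrial RNA content of the replicate 1 pool stays open for the shift that the 13 genes share, and no other biological explanation was tested.

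Immunoglobulin reads fell on few variable genes. A single gene of the Igkv1 family held 99.96% of kappa variable counts in replicate 1, and Igkv4-55 held 58.3% in replicate 2 beside Igkv5-39, where the heavy chain gene Ighm was also higher (64.5 and 2157 TPM). The kappa signal of replicate 1 had few heavy chain counts beside it, with 75504 on Igkc against 2924 on Ighm. Heavy variable genes had 791 counts there against 60195 on kappa variable genes. In replicate 2 Igkc had 27515 counts against 53975 on Ighm, and heavy variable genes had 9538 against 18718 on kappa variable genes. Of other heavy chain constant genes, Igha, Ighd and Ighg2b had no counts in replicate 1 and 3, 100 and 33 in replicate 2. Of the 12 genes of the B cell list, 3 were detected in replicate 1, all of them also in replicate 2, where 9 were detected. Igll1 (0 and 118 counts), Cd79b (0 and 114), Pax5 (0 and 89) and Ebf1 (1 and 244) were among those detected in replicate 2 alone, and their source was not tested. Antibody RNA from a large and diverse B-lineage population, as free RNA or library carry-over, would spread over many genes, but the effective number of kappa variable genes was 1.00 in replicate 1 and 1.97 in replicate 2, with the Igkv1 family gene (7824 TPM in replicate 1) above Eef1a1 (5932 TPM). These effective numbers restate the pattern seen first. They argue against a diverse source only as far as reads were assigned correctly, as read sharing between variable genes was not tested. The top kappa variable gene of replicate 1 held 0.625% of the kappa variable counts of replicate 2, and that of replicate 2 held 0.0166% of those of replicate 1, but the pattern was found on these same counts, so they do not decide whether a few antibody-expressing cells among the 100 of each pool were the source. Of 14 genes of antibody-secreting cells, 7 were detected in both libraries and 12 in replicate 2. Jchain (99.4 and 129 TPM) and Xbp1 (33.7 and 38.6 TPM) were among the 7. In replicate 1 Irf4, Derl3 and Tnfrsf17 had no counts, and Prdm1 (0.26 TPM) and Eaf2 (0.53 TPM) were not detected. Fkbp11, without counts in either library, and Mzb1 (0 and 13 counts, 0.92 TPM in replicate 2) were detected in neither. A few antibody-expressing cells as a source therefore remain an open hypothesis, and the gate that isolated the cells is not given in the sources used here.

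Several neutrophil granule and alarmin genes appeared in replicate 2 nearly alone, with Ngp at 3 and 2605 counts, Fcnb at 0 and 753, S100a9 at 3 and 487, Lcn2 at 1 and 429, Ltf at 0 and 362, S100a8 at 0 and 214 and Camp at 2 and 201. Lower sequencing depth of replicate 1 is argued against by its nuclear coding counts, 1.88 times those of replicate 2. Fewer molecules recovered in replicate 1 would leave other genes of the same replicate 2 level as empty, but 0% of 10000 matched random sets had as many members at 3 counts or fewer as the 6 of 8 observed, the highest having 3. That list was chosen for this gap. The random sets also drew genes singly, not genes expressed together, so the share alone cannot decide on recovery. Of a second set of granulocyte genes, 9 were detected in replicate 2 and 55.6% of these (5, including Chil3, Hp and Cd177) were at 3 counts or fewer in replicate 1, which 0% of matched sets reached, while Pglyrp1 and Cybb were detected in both libraries, as were Padi4 (26.9 and 11.03 TPM) and Anxa1 (29.1 and 20.3 TPM), which were higher in replicate 1. Cells of the granulocyte lineage that express these genes, in the replicate 2 pool alone, are a candidate source of them, and the stage of such cells was not tested. Ngp (139.5 TPM) and S100a9 (69.1 TPM) were the most abundant members of the mature list in replicate 2, and a stem cell gate would be meant to remove such cells. Early granule genes were present in both libraries, with Mpo at 246 and 891 TPM and Elane at 172 and 463 TPM. Free RNA or library carry-over was not tested for the granule and alarmin genes seen nearly in replicate 2 alone, so their source stays open.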
